A study of Mus musculus with 8 samples.

How the data were processed

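RNA was sequenced from olfactory bulbs of mice at postnatal day 30. The labels place 4 libraries in the double mutant group, which carries hGFAP-Cre with floxed alleles of Sp8 and of Sp9, and 4 libraries in a group of wild-type littermates. The hGFAP-Cre transgene expresses Cre recombinase from a human GFAP promoter, which is active in radial glia, the neural stem cells of the developing brain, and in astrocytes. Flanking loxP sites let Cre remove a part of each floxed gene in those cells and in all cells that descend from them. The mice had a mixed C57BL/6J, 129S6 and CD1 background. The labels also give each library a letter, A or B in the double mutant group and C or D in the wild-type group, with 2 libraries per letter. They do not state whether the libraries of a letter came from the same animal, so p-values measure the spread between these libraries, which may in part be technical.

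A single series table holds a pair of measurements per library. FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) were deposited by the authors for each library, and the submitters' processing notes name TopHat, Cufflinks 2.1.1 and the build GRCm38.p4, without a role or order. The annotation, the strand setting and any filter are not given in the sources used here. A second column per library, headed as a count, was deposited as a scaled signal. In each library 98.2% to 98.4% of its values were whole multiples, within 0.02 of a step, of a step that lay between 0.7363 and 1.2465 and differed between libraries. The totals of these columns lay between 13862257 and 14847428, and in steps they came to between 11888674 and 19040795, which was taken as the approximate number of fragments. Because the remaining values were not whole, no count model was used, and the scaled columns served only for depth, for a comparison of library pairs and for an alternative fit.

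The table holds 19583 entries named by gene symbol, of which 18342 (93.7%) carry a symbol of GENCODE M21. In 27 entries the symbol reads as a calendar date, 2 symbols are held by more than 1 entry, and 1 entry is 0 in every library. None of the 10 mitochondrially encoded genes that had been listed was in the table analysed here, so mitochondrial RNA was not analysed here. Coordinates are from GENCODE M21 on GRCm38, counted from 1. Annotated exons of 11 of the 92 named genes overlap exons of another gene in the table on the opposite strand, and without a stated strand setting the reads of the overlap cannot be assigned. These 11 genes are Alas2, Bmp4, Csf1r, Gabra5, Gng13, Gpr17, Rarres2, Scgb1c1, Sp9, Ube2c and Xist. Haemoglobin genes and H2 genes share sequence with close paralogs, so their single values are uncertain.

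Values were analysed as log2(FPKM + 0.5) for the 14349 genes with a mean of at least 0.5 FPKM over the 8 libraries. A linear model with the group as its only term was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean expression. Two-sided p-values were adjusted by the Benjamini-Hochberg method over the 14349 genes, and a gene was called at an adjusted p below 0.05. Fold changes are double mutant over wild type on the log2(FPKM + 0.5) scale, which understates the change of genes with low values. Single genes of prior interest were also tested with an exact two-sided permutation test over the 70 assignments of 8 libraries to groups of 4. Its smallest possible p is 0.0286. It treats single libraries as exchangeable, which may not hold for libraries of the same letter. Gene lists were tested with camera from limma, two-sided, at a preset correlation between genes of 0.01, adjusted over the 23 lists with at least 3 tested members. As alternatives the correlation was estimated for each list, and fry, which tests whether the genes of a list move in a common direction without comparing them with other genes, was run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

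The groups, the fit, the alternatives, 25 gene lists with 240 members and the rule for naming genes were fixed before the data were examined. Of the 240 members, 229 were in the table. The rule names Sp8 and Sp9, then Prokr2, Tshz1, Gad1, Gad2, Th, Calb1, Calb2 and Pvalb, then the 10 called genes with the largest change in each direction that had a mean of at least 1 FPKM in the higher group, no overlap between the groups and a symbol other than those of predicted genes, clones, pseudogenes, small RNAs and olfactory receptors, and from each list the 3 members with the smallest p and the member with the highest mean FPKM. Some genes that this rule takes are not reported here. Any other gene named below was chosen after its values were seen.

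Pairs of libraries were compared with a chi-square per gene on the scaled columns in steps, over genes with a sum of at least 20. The median chi-square relative to its expectation under sampling noise was 1.17 to 1.45 for libraries of the same letter, 1.57 to 2.36 for libraries of the same group with different letters and 10.33 to 13.83 between the groups. All pairs thus differed by more than sampling noise, so no library is a copy of another, and each was counted as a replicate as the labels number them. This does not show that libraries of a letter come from separate animals, and if they do not, the p-values measure in part a spread between libraries that may be technical. Because libraries of the same letter were the most alike, fits with the letter as a random block and on the mean of each letter were compared with the fit to single libraries. In the fit with the letter block, lists were tested with cameraPR on the moderated t values at the preset correlation, not with camera. A list result under that fit can therefore differ because of the test and not only because of the block.

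The fit was tested on simulated data for the comparison of double mutant with wild type, with 14349 genes of which 200 were changed. With independent libraries it recovered 79% of the genes changed by 0.5 and 97% of the genes changed by 1 on the log2 scale. It made 8 false calls, or 4.3% of its calls, against 8.2% with the letter block. With libraries of the same letter made to vary together, false calls made up 13.9% of calls in the fit to single libraries. They made up 8.8% with the letter block, and neither fit called a gene where none had been changed. The simulation changed 200 genes, evenly in both directions, while 9364 were called in the data, so these rates may not hold for the data. Each setting was simulated with a single data set, so the rates have no spread and do not rank the fits. Alternatives covered the pseudocount, the filter on low values, the scaling of the columns, the moderation, sample weights, replicate and letter blocks and the removal of each library. The scaled columns with a pseudocount of 10 and the removal of each letter were added after the data were seen. The planned comparisons with a second count model and with calls by the authors were not run, since the columns used are not raw counts and no table of calls was used here.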

Results

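The bulb-wide RNA levels of 8 mouse olfactory bulb samples at postnatal day 30 were measured by RNA sequencing, with 4 libraries from double mutants that lack Sp8 and Sp9 in the hGFAP-Cre lineage and 4 libraries from wild-type littermates. The olfactory bulb is the first relay of smell in the brain, and it keeps receiving new inhibitory interneurons after birth. Sp8 and Sp9 are zinc finger transcription factors of the Sp family that are expressed in these interneurons and their precursors. The comparison asks which genes differ in the bulb between these groups. The labels name hGFAP-Cre and the floxed alleles in the double mutants only. For every gene, effects of the transgene or the floxed alleles and of the loss of both factors therefore cannot be told apart. Depth came to between 12453491 and 19040795 fragments in the double mutant libraries and between 11888674 and 15992146 in the wild-type libraries, estimated from the step size of the scaled columns. Between 13112 and 13481 genes reached at least 1 FPKM in a library. The first principal component held 74.1% of the variance and separated the groups, and the second held 7.9% and separated the double mutant libraries of letter A from those of letter B.

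Both targeted genes were lower in every double mutant library than in any wild-type library. Sp8 (chromosome 12, 118846329 to 118852576, plus strand) measured 7.22, 6.15, 7.65 and 8.06 FPKM in double mutant replicates 1 to 4 and 31.57, 31.23, 29.98 and 29.34 FPKM in the wild-type replicates. Sp9 (chromosome 2, 73271925 to 73284706, plus strand) measured 7.12, 6.24, 6.32 and 7.27 FPKM in the double mutants and 23.15, 24.33, 25.30 and 23.66 FPKM in the wild type. The double mutant means were 23.8% of wild type for Sp8 and 27.9% for Sp9, with log2 fold changes of -2.0 ± 0.07 (SE, n = 4 per group, limma adjusted p = 5.73e-09) and -1.77 ± 0.06 (limma adjusted p = 3.66e-09). An exact permutation test, which treats single libraries as exchangeable, gave p = 0.0286 for each gene, the smallest value that 4 against 4 libraries can give. FPKM values per gene sum over all exons, so they do not show which part of the remaining RNA lacks the deleted exons. Annotated exons of Sp9 overlap exons of Cir1 on the opposite strand by 270 bases.

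**Figure D1:**
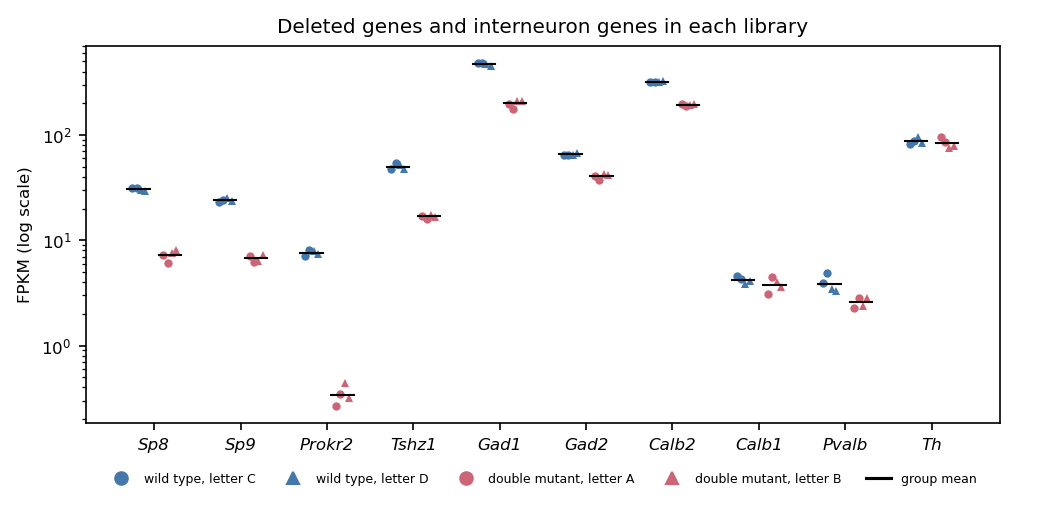
FPKM of Sp8, Sp9 and the interneuron genes of prior interest in each of the 8 libraries, on a log axis, with wild-type libraries in blue, double mutant libraries in red, letters A and C as circles, letters B and D as triangles, and group means as bars. Sp8 fell from a mean of 30.53 to 7.27 FPKM and Prokr2 from 7.63 to 0.343 FPKM, while the libraries of the groups overlapped for Th and Calb1.

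In the double mutant bulb, the lists of genes of GABA synthesis, interneuron subtypes and migrating neuroblasts were lower, and those of projection neurons, astrocytes, microglia, vessels, meninges and dividing cells were higher, in tests at a preset correlation between genes. None of them passed with an estimated correlation, where the lowest adjusted p was 0.0687, and the dopamine, oligodendrocyte and oligodendrocyte precursor lists did not pass at the preset one either. The genes with the largest falls included the prokineticin receptor gene Prokr2, which guides neuroblasts out of the migratory stream, the metabotropic glutamate receptor gene Grm4, the GABA-A receptor subunit gene Gabra5 and the opioid peptide gene Penk. The largest rises included the sperm protamine gene Prm1 and the proliferation genes Ube2c, Top2a, Ccnb1, Rrm2 and Pbk. Of 14349 genes tested, limma called 65.3%, with 4127 higher and 5237 lower in the double mutant. Counts of called list members below are to be read against that share. No overlap between the 4 and 4 values was seen for 8476 of the 14349 tested genes, where exchangeable libraries give 2.9% of genes. At least a 2-fold change on the log2(FPKM + 0.5) scale was seen for 243 called genes that were higher and 300 that were lower. Under upper quartile scaling of the columns the split turned to 5123 higher and 3820 lower, so the share of higher calls went from 44.1% to 57.3%. The genes with at least a 2-fold change then split into 364 higher and 241 lower, and into 282 and 273 under trimmed mean scaling. The balance between the directions thus depends on the scaling for small and large changes. For changes of at least 2-fold it also depends on the pseudocount, with 479 higher and 372 lower at 0.1 and 149 and 253 at 1. With the letter as a random block 3723 genes were higher and 4748 lower, and 8471 of the 9364 calls were kept with the same sign.

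**Figure D2:**
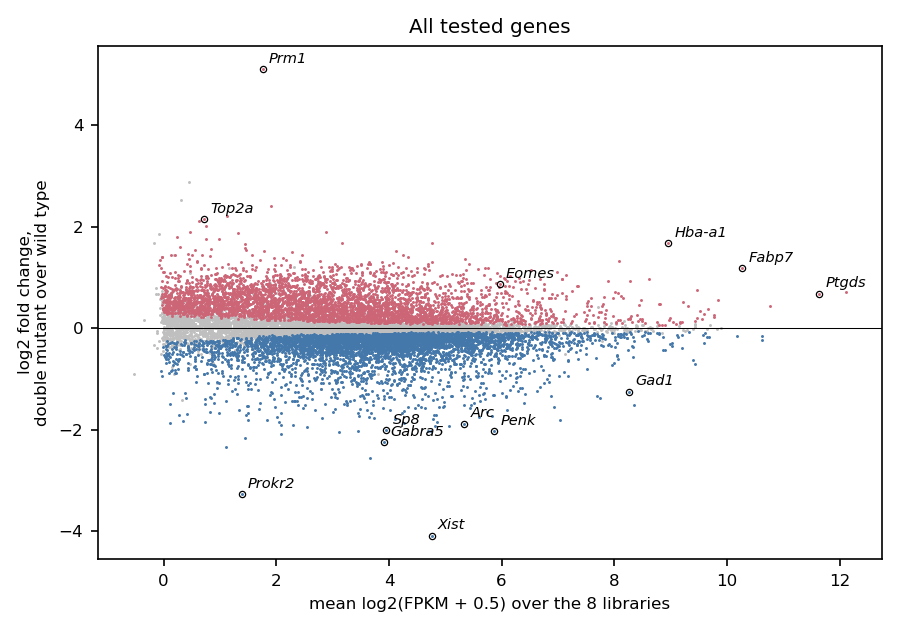
Log2 fold change of double mutant over wild type against the mean log2(FPKM + 0.5) of the 8 libraries for the 14349 genes tested, with called genes in red (higher) or blue (lower), other genes in grey and 13 labelled genes. Prm1 lies highest at 5.11, and Prokr2 at -3.27 and Xist at -4.09 lie lowest among the labelled genes.

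Among the 10 largest falls that the naming rule took, Prokr2 (chromosome 2, 132337733 to 132385447, minus strand) dropped to 4.5% of its wild-type mean, from 7.63 ± 0.41 to 0.343 ± 0.074 FPKM (SD, n = 4), with a log2 fold change of -3.27 ± 0.08 (SE, limma adjusted p = 1.33e-09). Grm4 fell by 2.55 and Gabra5 by 2.25 on the log2 scale. The neurotrophic factor gene Artn fell by 2.35 and the metalloprotease gene Adamts19 fell by 2.17. The synaptotagmin gene Syt10 fell by 2.03 and Penk fell by 2.02. Sp7, another Sp family gene known as a regulator of bone formation, fell by 2.04, from 17.12 ± 0.99 to 3.79 ± 0.38 FPKM. The immediate early gene Egr2 fell by 2.09. Xist, the X-inactivation RNA of females, had the largest change at -4.09 ± 1.58 (limma adjusted p = 0.0411), but it measured 0.04 to 0.05 FPKM in the libraries of letter B and 76.85 to 79.96 FPKM in those of letter A. Its adjusted p rose to 0.11 without double mutant replicate 3 and to 0.109 without replicate 4, where the change was -2.90 and -2.88, and to between 0.0697 and 0.0743 when any wild-type library was left out, and it was 0.136 on the means of the letters. Without letter B, which was chosen after the data were seen, the change in Xist was -0.50.

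Among the 10 largest rises, Prm1 (chromosome 16, 10796326 to 10805839, minus strand) reached 19.49 ± 2.39 FPKM in the double mutants (SD, n = 4), against 0.39 FPKM in wild-type replicate 1 and values listed at 0 in the other 3 wild-type libraries. Its log2 fold change was 5.11 ± 0.18 (SE, limma adjusted p = 5.67e-09), but 7.04 with a pseudocount of 0.1 and 2.47 in the scaled columns. The scaled columns were fitted with a pseudocount of 10, and a larger pseudocount shrinks the changes of low genes by construction. Top2a, the topoisomerase of dividing cells, rose by 2.15 ± 0.10 on the log2 scale, from 0.284 ± 0.067 to 2.98 ± 0.22 FPKM. The ubiquitin-conjugating enzyme gene Ube2c rose by 2.22, the cyclin gene Ccnb1 by 1.90, the ribonucleotide reductase gene Rrm2 by 1.88 and the mitotic kinase gene Pbk by 1.76. The chromatin regulator gene Prdm8 rose by 2.12, the thrombospondin gene Thbs4 by 1.79 (2.98 with a pseudocount of 0.1) and Clca1 by 1.69. The secretoglobin gene Scgb1c1 rose by 2.02 ± 0.42 with a wide spread in the double mutants, 3.43 ± 2.58 FPKM. Its change was 2.98 with a pseudocount of 0.1 and 0.84 in the scaled columns with their pseudocount of 10.

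Transcription factors of bulb interneurons were mostly lower. Of 17 tested members, 12 fell, 3 rose and 2 did not pass the test, with a median log2 fold change of -0.80 (camera adjusted p = 0.00381, and adjusted p = 0.115 with an estimated correlation). Meis2 fell to 29.9% of its wild-type mean, from 102.4 ± 2.5 to 30.6 ± 2.2 FPKM (SD, n = 4), Dlx5 fell by 1.37 and Tshz1 (chromosome 18, 84011627 to 84087706, minus strand), which acts in the exit of neuroblasts into the bulb layers, fell by 1.55 on the log2 scale. The members that rose do not do what the fall of the list would say. Among them were Gsx2, a factor of ventral progenitors (1.41), and Nr2f2, which is also expressed in vessels and other cells (1.18). Pax6, a factor of dopaminergic periglomerular cells and their precursors, measured 14.9 ± 0.4 FPKM in double mutants and 15.4 ± 0.9 FPKM in wild type and did not pass the test. Of 6 tested members of the other Sp family genes, 4 fell and 1 rose. Sp7 and Sp4 fell by 2.04 and 0.60, Sp3 fell by 0.20 (-0.11 under upper quartile scaling) and Sp1 rose by 0.27. The list did not pass (median -0.39, camera adjusted p = 0.135), nor on the means of the letters or with an estimated correlation (adjusted p = 0.244). It passed with fry (adjusted p = 1.92e-06). It also passed with the letter block (cameraPR adjusted p = 0.0292), where the block cannot be told apart from the change of test.

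All 4 genes of GABA synthesis and transport fell. The glutamate decarboxylase genes Gad1 and Gad2 went from 473 ± 13 to 199 ± 18 FPKM and from 65.8 ± 1.4 to 40.5 ± 2.3 FPKM (SD, n = 4), which are log2 fold changes of -1.25 ± 0.06 and -0.70 ± 0.04 (SE). The vesicular GABA transporter gene Slc32a1 fell by 1.18. The list median was -0.94 (camera adjusted p = 0.00159, and adjusted p = 0.166 with an estimated correlation). Of 10 interneuron subtype markers, 7 fell, 1 rose and 2 did not pass (median -0.39, camera adjusted p = 0.00502, and adjusted p = 0.131 with an estimated correlation). The granule cell genes Penk and Synpr fell by 2.02 and 1.56, the calretinin gene Calb2 fell by 0.72 and the parvalbumin gene Pvalb by 0.49 (-0.32 without letter C). The calbindin gene Calb1 measured 3.80 ± 0.58 FPKM in double mutants and 4.19 ± 0.30 FPKM in wild type, a difference within the spread of the libraries (exact permutation p = 0.2857, n = 4 per group). The somatostatin gene Sst was the member that rose, by 0.62 ± 0.18.

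The dopamine genes did not follow the GABA genes. Th, the rate-limiting enzyme of dopamine synthesis, measured 83.5 ± 8.8 FPKM in double mutants and 86.9 ± 5.9 FPKM in wild type (SD, n = 4), with a log2 fold change of -0.06 ± 0.07 (SE, limma adjusted p = 0.476, exact permutation p = 0.5429). This sign turned to 0.03 under upper quartile scaling and under quantile normalization, and to 0.06 without letter B. Without letter A the change was -0.18 and passed the test (limma adjusted p = 0.0308). Of the 8 members of the dopamine list, 4 rose and 4 did not pass, with the monoamine transporter gene Slc18a2 up by 0.54, Spr up by 0.36 and the receptor gene Drd2 up by 0.47. The list did not pass (median 0.24, camera adjusted p = 0.109) but did with fry (adjusted p = 0.000218), and its median was 0.05 with the filter at 2 FPKM.

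Genes of migrating neuroblasts fell as a list, with 10 of 13 members lower, 3 not past the test and a median of -0.52 (camera adjusted p = 0.00159, and adjusted p = 0.2 with an estimated correlation). Adjusted over the list alone, 11 members were lower and 1 was higher. The doublecortin gene Dcx, a marker of migrating neuroblasts, fell to 30.0% of its wild-type mean, from 51.1 ± 1.7 to 15.3 ± 0.9 FPKM (SD, n = 4). Cd24a fell by 0.61 on the log2 scale, and the neuronal tubulin gene Tubb3 fell by 0.17, which no longer passed under upper quartile scaling, on the means of the letters or without letter A or D. Cell cycle genes went the other way, with 9 of 10 tested members higher and a median of 1.26 (camera adjusted p = 2.18e-05, and adjusted p = 0.0687 with an estimated correlation). Top2a, Ccnb1 and Mki67 rose by 2.15, 1.90 and 1.45 from wild-type means of 0.284, 0.221 and 0.165 FPKM. At such low levels the size depends on the pseudocount, and these changes were 3.02, 2.87 and 2.42 with a pseudocount of 0.1 and 1.63, 1.39 and 0.99 with a pseudocount of 1, where the list median was 2.06 and 0.93. Pcna, which also acts in DNA repair, measured 20.2 ± 1.6 and 19.6 ± 0.7 FPKM and did not pass, although it passed under quantile normalization (0.13, limma adjusted p = 0.0455).

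Markers of the projection neurons of the bulb, the mitral and tufted cells, were higher. Of 9 members, 7 rose and 2 did not pass (8 rose adjusted over the list alone), with a median of 0.74 (camera adjusted p = 9.39e-05, and adjusted p = 0.0687 with an estimated correlation). Eomes rose from 45.6 ± 0.6 to 84.0 ± 3.5 FPKM (SD, n = 4), and the vesicular glutamate transporter genes Slc17a6 and Slc17a7 rose by 0.90 and 0.56 on the log2 scale. Doc2g measured 293 FPKM in both groups, with a change of 0.00 ± 0.03 (SE). Of 9 tested cortical neuron markers, which would show tissue next to the bulb in the dissection, 6 rose and 3 fell (median 0.38, camera adjusted p = 0.27, and adjusted p = 0.00238 with fry). Cux2 rose by 0.52, while Nrgn and Bcl11b, which bulb granule cells also express, fell by 1.76 and 0.50.

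Markers of the nerve layer and of the coverings of the bulb rose as well. Of 8 tested olfactory sensory neuron markers, 5 rose and 3 did not pass (median 0.55, camera adjusted p = 0.0107, and adjusted p = 0.244 with an estimated correlation), with Gng13, Stoml3, Omp and S100a5 up by 0.93, 1.21, 0.90 and 0.72. Of 5 olfactory ensheathing cell markers 4 rose (median 0.97, camera adjusted p = 0.00159, and adjusted p = 0.189 with an estimated correlation). Fabp7, a fatty acid binding protein gene of ensheathing and radial glia, rose from 823 ± 62 to 1869 ± 111 FPKM (SD, n = 4). All 8 meningeal and fibroblast markers rose (median 0.94, camera adjusted p = 1.97e-05, and adjusted p = 0.131 with an estimated correlation), with the collagen genes Col3a1 and Col1a2 up by 1.14 and 0.99 and the transporter gene Slc6a13 up by 0.92. Ptgds, the gene with the highest level of the list, rose by 0.68, but it ranked second of all genes in every library, and its difference was 0 under quantile normalization, which sets equal ranks to equal values. Of 5 tested blood genes, 3 rose, with Hba-a1, Hbb-b1 and Alas2 up by 1.67, 1.31 and 1.15, and the list did not pass (median 1.15, camera adjusted p = 0.0694). It passed with the filter at 2 FPKM, with fry, without letter C, and without wild-type replicate 2 or 3.

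All 11 astrocyte markers rose, with a median of 0.59 (camera adjusted p = 7.07e-06, and adjusted p = 0.115 with an estimated correlation). The gap junction gene Gja1 rose from 95.9 ± 1.8 to 189 ± 5 FPKM (SD, n = 4) and the water channel gene Aqp4 by 1.02 on the log2 scale, while the glutamate transporter gene Slc1a3 and Aldoc rose by 0.48 and 0.26. Of 12 tested reactive astrocyte genes, 10 rose and 1 fell (median 0.86, camera adjusted p = 0.00101, and adjusted p = 0.131 with an estimated correlation), with Vim, H2-D1 and Gbp2 up by 0.93, 0.83 and 1.04. The member that fell was S100a10, which neurons also express. Microglia and endothelial markers rose in the same libraries, with medians of 0.43 and 0.61. The cells behind the members that rose therefore cannot be told either. Of 14 microglia markers, 11 rose and 3 did not pass (12 rose adjusted over the list alone), with a median of 0.43 (camera adjusted p = 8.07e-05, and adjusted p = 0.144 with an estimated correlation). Ctss and Csf1r rose by 0.64 and 0.53.

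Of 12 endothelial and mural markers 11 rose (median 0.61, camera adjusted p = 1.97e-05, and adjusted p = 0.114 with an estimated correlation), with the tight junction gene Cldn5 up by 1.03, Vtn by 0.96 and Cdh5 by 0.73. The 3 tested ependymal markers rose, with Foxj1, the regulator of motile cilia, up by 0.97, Rsph1 by 0.67 and Rarres2 by 0.62, or 0.40 without letter A (median 0.67, camera adjusted p = 0.0171, and adjusted p = 0.165 with an estimated correlation). Oligodendrocyte markers moved less. Of 12 members 5 rose, 1 fell and 6 did not pass (median 0.12, camera adjusted p = 0.0518, and adjusted p = 0.461 with an estimated correlation). Sox10, which ensheathing glia also express, rose by 1.07, Olig2 rose by 0.39, and the myelin gene Mbp measured 858 ± 105 FPKM in double mutants and 818 ± 30 FPKM in wild type. Mbp passed without double mutant replicate 1 (0.14, limma adjusted p = 0.0419) and without letter A (0.20, limma adjusted p = 0.00688). The list passed under several alternatives, among them the other scalings, fry, and the fits without double mutant replicate 1 or 2, wild-type replicate 4 or letter A. It also passed with the letter block, where cameraPR was used instead of camera. It did not pass on the means of the letters, and its median was 0.004 without letter B. Of 5 oligodendrocyte precursor markers, 4 rose, among them Pdgfra, Gpr17 and Bmp4 by 0.32, 0.38 and 0.68, and the list did not pass (median 0.32, camera adjusted p = 0.0674), but it passed with fry (adjusted p = 0.000778), without double mutant replicate 3 (adjusted p = 0.0447) and without letter B (adjusted p = 0.0409).

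**Figure D3:**
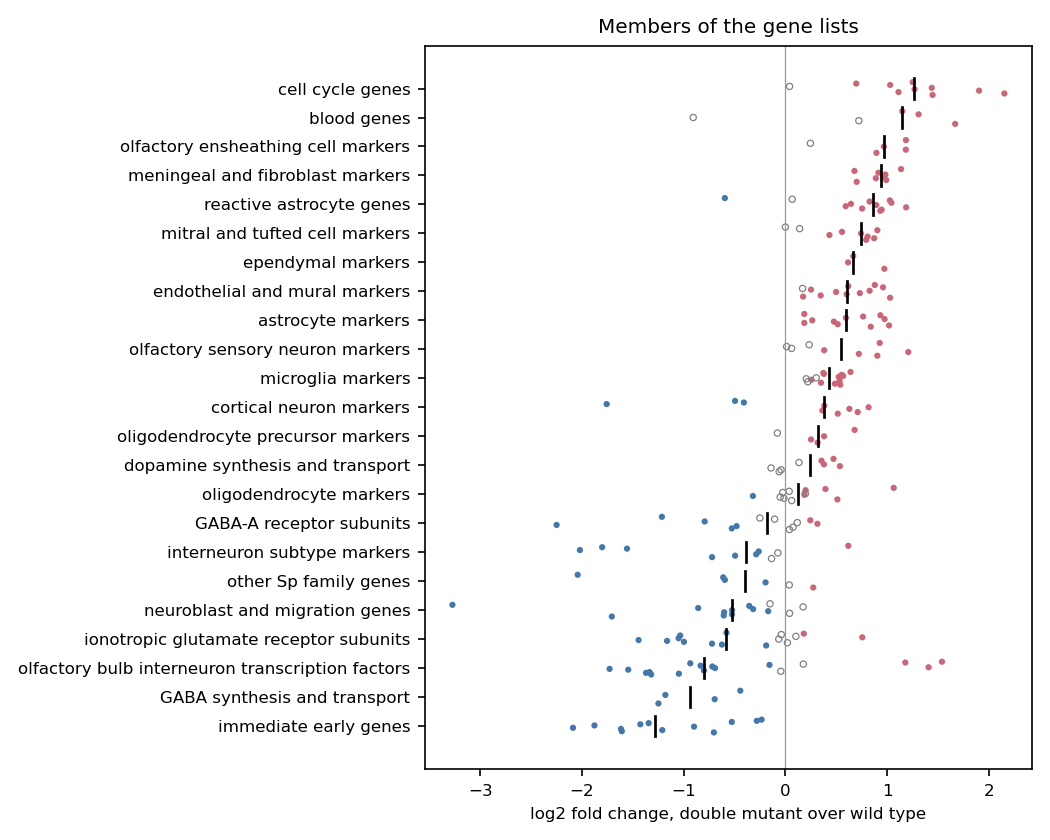
Log2 fold change of double mutant over wild type for each tested member of the 23 gene lists with at least 3 tested members, with called members in red (higher) or blue (lower), other members as open circles and the list median as a black bar. Medians run from -1.28 for immediate early genes to 1.26 for cell cycle genes.

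All 12 immediate early genes, which neurons switch on with activity, fell (median -1.28, camera adjusted p = 1.36e-05, and adjusted p = 0.114 with an estimated correlation). Arc fell from 77.0 ± 3.1 to 20.6 ± 1.7 FPKM (SD, n = 4), and Egr1 and Egr2 fell by 1.62 and 2.09 on the log2 scale. Of 15 ionotropic glutamate receptor subunits, 9 fell, 2 rose and 4 did not pass (median -0.58, camera adjusted p = 0.0107, and adjusted p = 0.165 with an estimated correlation). The NMDA receptor subunit gene Grin1 fell from 157 ± 4 to 78.6 ± 2.9 FPKM, Grik2 and Gria2 fell by 1.03 and 0.62, and Grin3a rose by 0.76. Of 12 GABA-A receptor subunits, 5 fell, 2 rose and 5 did not pass. The list did not pass (median -0.18, camera adjusted p = 0.105), nor on the means of the letters or with an estimated correlation (adjusted p = 0.472). It passed without letter B (camera adjusted p = 0.0251) and with fry (adjusted p = 1.46e-05). It also passed with the letter block (cameraPR adjusted p = 7.1e-05), where the block cannot be told apart from the change of test. Gabra5 fell by 2.25 and Gabrd by 1.21.

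Each list median kept its sign under each scaling, pseudocount, filter and left-out library in which the list was tested, except the cortical median, which was -0.01 with the filter at 2 FPKM. The cell cycle list had too few members above that filter to be tested there. Apart from the neuroblast, mitral and tufted cell and microglia lists, the counts adjusted over the list alone equalled those over all genes. No list passed with an estimated correlation, where the lowest camera adjusted p was 0.0687, so the list calls rest on the preset form of camera. The value of the correlation does not explain this for every list. Estimates reached 0.691 for ensheathing cell markers. They were -0.009 for cell cycle genes and 0.012 for mitral and tufted cell markers, near the preset 0.01, and these lists did not pass either. Whole tissue was sequenced, so each value is a mean over all cells of the sample, and the lists of interneuron, glial, vascular and meningeal genes moved between the same libraries.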

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

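In each group of 4 libraries, a named gene was singled out here when the library at an end of the group stood far from the other 3 relative to the range of the group. This happened in 10 of 184 groups, where chance alone gives about 9.2, and no explanation was tested for any of them.

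In the wild-type group, Gad2 was highest in replicate 4 at 67.87 FPKM against 64.87 to 65.18 FPKM in the other 3 libraries, Tubb3 was highest in replicate 3 at 327.9 FPKM against 294.94 to 297.68, and Gabrd was highest in replicate 2 at 24.61 FPKM against 24.00 to 24.03. Wild-type replicate 3 was lowest for Slc17a6 at 9.49 FPKM against 10.80 to 11.09 and for Aqp4 at 41.18 FPKM against 43.87 to 44.15, and wild-type replicate 1 was lowest for Grin3a at 7.47 FPKM against 7.85 to 7.91. Prm1 was listed at 0.39 FPKM in wild-type replicate 1 and at 0 in the other wild-type libraries. In the double mutant group, Slc17a6 was highest in replicate 3 at 21.20 FPKM against 19.81 to 19.97, Grin3a was highest in replicate 1 at 14.02 FPKM against 13.24 to 13.35, and Alas2 was highest in replicate 4 at 4.93 FPKM against 3.81 to 3.88. The group means of Tubb3 were 271 FPKM in double mutants and 304 FPKM in wild type, so its gap was close to the difference between the groups.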

How the results depend on the processing

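The fits on scaled columns and without both libraries of a letter were chosen after the data were seen, and the others were planned. Over all of them 3284 to 5123 genes were higher and 3820 to 5237 lower, and no more than 1 called gene was called with the other sign. Leaving out each library in turn gave 3858 to 3969 higher and 4800 to 5095 lower, with 233 to 259 and 288 to 316 at least 2-fold higher and lower. The genes at least 2-fold higher and lower, 243 and 300, became 479 and 372 with a pseudocount of 0.1, 149 and 253 with a pseudocount of 1, 397 and 315 in the scaled columns, 364 and 241 under upper quartile scaling and 282 and 273 under trimmed mean scaling, so the larger side turned in 4 of these. A larger pseudocount shrinks the fold changes of low genes by construction. Lists called, 16 of 23, became 0 with an estimated correlation, while fry called 23. No other alternative ended the call of a list that it tested, but the cell cycle list was not tested with the filter at 2 FPKM, where too few members stayed. The median of the cortical list, which had not passed, turned to -0.012 with the filter at 2 FPKM, where fewer members were tested. The other Sp family, oligodendrocyte, oligodendrocyte precursor, GABA-A receptor and blood lists passed in some alternatives.

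With the replicate number as a block, 4045 genes were higher and 5144 lower, and no list or named gene changed its call. Libraries with the same number did not deviate together across the groups (correlations of -0.052, 0.001, 0.005 and -0.03), so the numbers do not pair them. With the letter means, 3491 genes were higher and 4202 lower, and 7648 of the 9364 calls were kept with the same sign. Deviations from the group mean were also correlated within the groups, where subtracting that mean pushes correlations below 0 by construction. They came to 0.148, 0.263, 0.042 and -0.206 for the libraries of letters A, B, C and D. Libraries of different letters gave -0.622 to -0.443, so only the order of these values is informative.

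Of 92 named genes, 86 kept their direction and their side of the threshold in every alternative that tested them, and Xist, Tubb3, Ptgds, Th, Mbp and Pcna did not. The sign of Th turned to 0.026 under upper quartile scaling, 0.034 under quantile normalization and 0.055 without letter B. Mbp turned to -0.031 under quantile normalization, -0.003 without double mutant replicate 4 and -0.072 without letter B. Pcna turned to -0.024 without letter B. With each library left out, Mbp ranged from -0.003 to 0.138. None of these 3 genes had passed the threshold, and the cause was not tested. Genes with a mean below 0.5 FPKM were tested only in the fit without a filter. A second count model and calls by the authors, both planned, were not run.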

Other observations

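The gene groups in this paragraph and the next, and all tests in this part, were chosen after the data were seen. Genes induced by interferons, the antiviral signals of the immune system, were higher in the double mutant. Of 21 tested members, 19 rose and 1 fell, with a median log2 fold change of 0.83 (camera adjusted p = 1.84e-06 over 8 such lists, and adjusted p = 0.202 with an estimated correlation). The chemokine gene Cxcl10 rose from 0.364 to 2.05 FPKM, Isg15 from 3.90 to 10.3 FPKM, Ifitm3 from 27.2 to 65.8 FPKM and Xaf1 from 2.11 to 5.58 FPKM (means, n = 4), and the exception was Mx2, which fell by 0.38. Markers of microglia, endothelium, reactive astrocytes and meninges, cells that express many of these genes, rose in the same libraries (medians of 0.43, 0.61, 0.86 and 0.94). Of 11 tested antigen presentation genes 9 rose (median 0.89, camera adjusted p = 0.000261, and adjusted p = 0.22 with an estimated correlation), with Cd74, the invariant chain of class II molecules, up by 1.67 ± 0.16 (SE) and B2m, the light chain of class I molecules, up by 0.87 ± 0.05. Close paralogs among the H2 genes make their single values uncertain.

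Of 36 tested collagen genes 27 rose and 4 fell (median 0.55, camera adjusted p = 3.36e-06, and adjusted p = 0.202 with an estimated correlation), and 3 of the 36 are also in the meningeal list. Of 237 solute carrier genes 113 rose and 49 fell (median 0.15, camera adjusted p = 0.000482, and adjusted p = 0.202 with an estimated correlation). Of 74 potassium channel subunit genes 39 fell and 22 rose, where 36.4% of the other genes were lower and 28.8% higher. The group did not pass (median -0.22, camera adjusted p = 0.0599). Kcna4 had a log2 fold change of -1.26 ± 0.06 (SE) and Kcng1 had one of 1.16 ± 0.06. Of 6 tested olfactory receptor genes 2 rose, where 28.8% of the other genes were higher (camera adjusted p = 0.226).

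The 8 libraries can be split into groups of 4 in 35 ways, and only the real split, 1 of 35, called as many as 9364 genes. The highest other split called 5 genes and 31 others called none. If single libraries are exchangeable, the real split has a share of 0.029, the smallest that 35 splits can give. This makes chance in the grouping an unlikely source of the count but does not exclude it. Libraries of a letter are more alike than others, and the splits that keep the letters together are 3, too few for a share under 0.05. The other such splits called 0 and 5 genes.

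Prm1 measured 17.0 to 22.7 FPKM in the double mutants and at most 0.39 FPKM in wild type. Spermatid RNA would bring the other abundant spermatid transcripts. The 5 other genes of a spermatid list that were in the table had a median log2 difference of -0.04, and Tnp2 stayed at or below 0.32 FPKM. The libraries of letter A, which lack reads of the 4 Y-linked genes above 0.03 FPKM, held Prm1 at the same level. The spermatid list as a whole did not pass (camera adjusted p = 0.616). Only 3 of its members were tested and Prm1 is among them, so this list test cannot decide the question. Some transgenes carry protamine sequence at their 3' end, so reads from the Cre transgene may be a source. Prm1 exceeded 1 FPKM in 4 of 4 double mutant libraries and in no wild-type library, which an effect of the deletions would give as well. Reads from the transgene and an effect of the deletions cannot be told apart here, because the same animals carry both.

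Log2 fold changes were above 0 in 81 of 87 tested markers of 10 lists of cells other than interneurons. A lower share of interneurons would raise all other cell types alike if each marker were specific to its cell type. The medians ran from 0.12 for oligodendrocytes to 0.97 for ensheathing cells. The changes differed between the lists (permutation p = 0.0002 over 10000 resamples of members, which are not independent). The resamples move genes, not libraries, and markers such as Sox10 are also expressed in other cells. The test therefore cannot decide whether a lower share of interneurons is the whole cause. The 21 surface markers (meninges, ensheathing cells, sensory neurons) had a median of 0.90 and the 66 inner markers 0.49. The difference was 0.41 (permutation p = 0.001 over resamples of members). The medians of meninges and ensheathing cells were 0.94 and 0.97, but that of sensory neurons was 0.55. This lay below mitral and tufted cells (0.74), ependyma (0.67), endothelium (0.61) and astrocytes (0.59). It lay above microglia (0.43), oligodendrocyte precursors (0.32) and oligodendrocytes (0.12). More surface tissue in the double mutant samples may contribute, but this test has the same limits and cannot decide it. Inner lists such as astrocytes and endothelium rose as well. The split into surface and inner lists was set by hand, and whether surface tissue also holds these cells was not tested. Their rise therefore does not decide the question. A smaller bulb, another dissection or a change within the glia stay open and untested, since neither bulb size nor cell numbers were analysed here.

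The lower mean of Xist and the higher means of Y-linked genes in the double mutants came from letter B. All 4 Y-linked genes, Ddx3y, Uty, Kdm5d and Eif2s3y, exceeded 1 FPKM in both libraries of letter B and stayed below 0.1 FPKM in the other 6, so letter B likely comes from a male and the others from females. Their list did not pass (camera adjusted p = 0.224). Without letter B, 88.5% of the called genes were called again with the same sign, against 84.1%, 84.3% and 83.5% without letter A, C or D. The calls kept without letter B do not rest on it, whatever its sex. For the calls lost without it, sex cannot be told apart from other differences of letter B or from the smaller number of libraries. Xist was still lower without letter B, at -0.50, and that difference has no tested explanation.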
